A study of Mus musculus with 2 samples.

How the data were processed

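Per the labels, 14837 mouse PDAC cells were grown in DMEM with 10% fetal bovine serum and 100 U/ml penicillin and then kept for 48 h in medium conditioned by CAFs or by 14837 cells. RNA was taken up in Trizol, and libraries were made from 2 ug of total RNA and sequenced on an Illumina instrument, 1 library per medium. Per the submitters' processing notes, HISAT2 2.1.0, StringTie and the mouse build mm10 were used, with no role given for each. How reads were turned into counts, the strand setting, the treatment of reads with several matches, the selection of RNA and the annotation are not given in the sources used here.

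The deposited values used here are whole-number counts per gene symbol, not scaled to a fixed total, made by the authors. The table had 2 value columns. The CAF column was tied to the CAF-medium library by that sample's title. The name of the other column matched the labels of neither library, and a column is not assigned by elimination, so 1 value column was not used in any step beyond a first look at its range. The comparison of the 2 media planned before the data were examined was therefore not made, and neither were its ratios, its lowest genes nor its scaling alternatives. Everything computed instead, namely levels in 1 library, their percentiles, thresholds, gene pairs and alternatives, was chosen after seeing the data. The 38 gene lists were fixed before the data were examined.

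Counts were divided by the library total of 21269197 and multiplied by 1000000 to give CPM. Exact Poisson 95% intervals were computed per gene, and exact binomial intervals for the ratio of counts of 13 pairs of genes. For a count of 0 the limit printed is 3 counts, a one-sided 95% limit, or 0.141 CPM. All of these cover counting error only, since sequenced reads can be copies of 1 molecule and there was no second culture. Low counts were multiples of 3 more often than the whole numbers in their range are, so the counts may not be plain read numbers. The Poisson and binomial intervals may then be too narrow. CPM was also divided by the length of all exons of the gene in kilobases, since longer genes collect more counts. That length can exceed the longest transcript, so ratios per kilobase depend on this choice.

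For each list, members with at least 10 counts were kept, and their median CPM was ranked among 10000 random lists of the same size drawn from all genes with at least 10 counts. The random lists were not matched on expression, because the level itself was measured. At least 3 members were required, which left 37 lists, and percentiles above 95 or below 5 were counted. Leaving out members under 10 counts raises the level of marker lists, so the number left out is given. In simulated counts over 11567 genes, 5.0% of 40 lists of 20 members passed the 95th percentile with no shift, 45.0% with members raised 2-fold and 95.0% with members raised 4-fold. Percentiles were recomputed with no minimum, with a minimum of 100 counts, per kilobase of exon, without the highest member, and over protein-coding genes with under 10% of windows shared.

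Genes that can share reads were marked with the GENCODE M21 annotation of mm10 (GRCm38), to which 21900 symbols (99.6%) matched. The longest transcript of each gene was split into 64-base windows every 16 bases, and the share found exactly in transcripts of other, non-overlapping genes is called the shared windows. The genome outside annotated transcripts was not searched. The share of exonic bases lying in exons of other genes on either strand was also computed. Coordinates are 1-based and span the annotated gene from first to last exon.

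Named genes follow a rule set before the data were examined, with the level in the place of the planned ratio: the 12 highest genes with at least 100 counts, leaving out clone and model names and genes of the mitochondrial genome, up to 4 of the highest members of each list, and 7 genes at any value. Some genes that meet this rule are not reported here. Partners in pairs, members named because they were near 0, and genes in the closing part outside the lists were chosen after their values were seen. The table held 26 entries whose symbols had turned into dates, with 0.23% of counts. They were left in the total, and the 2 date names used by 2 entries each were left out of lists and random draws. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.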

Results

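RNA was sequenced from 14837 cells, a mouse pancreatic ductal adenocarcinoma (PDAC) line from the C57BL/6 strain, after 48 h in conditioned medium. Conditioned medium is culture medium that other cells have grown in, with whatever they released into it. The labels describe 2 libraries, 1 per medium. In 1 of them the medium came from cancer-associated fibroblasts (CAFs), the stromal cells of pancreatic tumours, and in the other from 14837 cells. Nucleosides released by the tumour's surroundings are the subject named in the series' title. The name of 1 value column in the deposited table matched the CAF-medium library. The name of the other matched neither library, so that column was not used and the 2 media were not compared. The values here are levels within the CAF-medium library. They show which genes were high or low in cells kept in CAF medium, and not how the medium altered them.

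The CAF-medium library held 21269197 counts over 21983 gene entries. Of these entries, 11569 had at least 10 counts and 8056 were listed at 0. The median gene among those with at least 10 counts had 806 counts, or 37.9 per 1000000 counts (CPM). With 1 library there was no replicate error, and no test between groups was made. Intervals are exact Poisson 95% intervals and cover counting error only. At 1000 counts such an interval ran from 939 to 1064 counts, and at 100 counts from 81.4 to 122. For a count of 0 the limit is set apart from these intervals at 3 counts, a one-sided 95% limit, or 0.141 CPM. Some genes of basic metabolism, among them the ATP synthase gene Atp5a1 and the respiratory chain gene Uqcrc1, were listed at 0, so a gene listed at 0 is not described as unexpressed.

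The highest gene was Eef1a1, an elongation factor of translation, at 5944 CPM (5912 to 5977), although 45.9% of its transcript windows were also found in other genes. Hspa5, the main chaperone of the endoplasmic reticulum, followed among the named genes at 3955 CPM (3929 to 3982). The ribosomal protein genes Rplp0 and Rpl4 stood at 3929 and 2052 CPM, with 33.3% and 10.8% of windows shared. Elongation factor Eef2 reached 2985 CPM, the poly(A)-binding protein gene Pabpc1 2052 CPM with 13.9% of windows shared, and the ribosome-associated Rack1 1948 CPM. The cytosolic chaperone Hsp90ab1 stood at 1962 CPM. The 12 highest named genes, which leave out the mitochondrial mt-Co1 at 5582 CPM, also included the secreted matrix protein osteopontin, Spp1, at 1931 CPM and the glycolytic enzyme Pkm at 1930.4 CPM. The epithelial keratin Krt18 reached 1819 CPM and the autophagy receptor Sqstm1 1781 CPM. Exons of other genes overlapped 18.8% of the exonic bases of Spp1 and 17.3% of those of Sqstm1, and 20.8% of the windows of Pkm were shared. The 10 highest genes held 3.23% of all counts and the 100 highest 13.4%.

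To describe groups of genes, the median CPM of each list's members with at least 10 counts was ranked among 10000 random lists of the same size. Of 37 lists with a percentile, 19 lay above the 95th percentile and 4 below the 5th. About 1.9 would lie above if the lists were random draws from all genes with at least 10 counts. These lists were chosen by function and some share members, such as Slc2a1, so 1.9 is no expectation for lists of this kind. The percentile describes this library only. The plot of member levels by list shows all 38 lists.

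**Figure D1:**
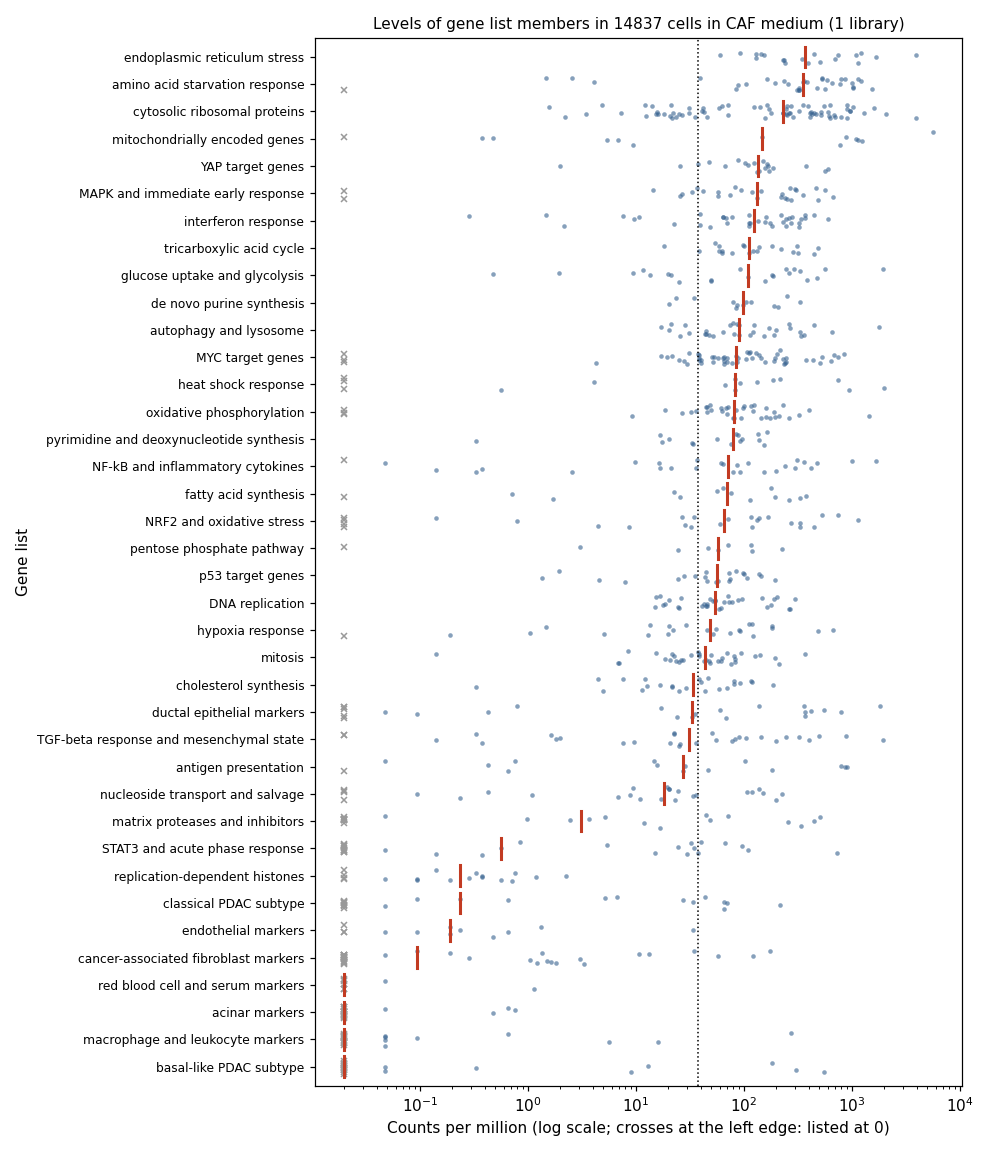
CPM (log scale) of every listed member of the 38 gene lists in the CAF-medium library; each point is 1 gene, crosses at the left edge are genes listed at 0, red bars are medians over all listed members and the dotted line is the median of genes with at least 10 counts (37.9 CPM). Endoplasmic reticulum stress genes, with a median of 371 CPM, stand at the top, and most members of the acinar, leukocyte and basal-like lists are listed at 0 or under 10 counts.

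Nucleoside handling was the part of metabolism closest to the study's question, and its transport and salvage genes were at modest levels. Of 26 listed genes, 19 had at least 10 counts, with a median of 23.2 CPM at percentile 14.1, and 6 exceeded the median gene. Slc29a1 and Slc29a2 encode equilibrative nucleoside transporters, which let nucleosides cross the cell membrane in either direction. Slc29a1 (chromosome 17, 45585200 to 45599606, minus strand, mm10) stood at 118 CPM (114 to 123). Slc29a2 (chromosome 19, 5023860 to 5031972, plus strand) stood at 17.1 CPM (15.4 to 18.9), so Slc29a1 had 6.93 times its counts (exact 95% interval 6.2 to 7.76) and 5.22 times its counts per kilobase of exon. The concentrative transporters, which take up nucleosides along with sodium, had few counts listed, with Slc28a1 at 2 counts and Slc28a2 and Slc28a3 listed at 0, and 32.4% of the windows of Slc28a2 were shared. The highest members were the purine salvage genes Aprt at 224 CPM (218 to 231) and Hprt at 198 CPM (192 to 204). Nt5e, the surface enzyme that makes adenosine from AMP, stood at 149 CPM (144 to 154), and the uridine-cytidine kinase Uck2 at 138 CPM. Uck2 had 1.3 times the counts of Uck1 but 0.655 times its counts per kilobase, so the order of that pair depends on length, and 20.5% of the windows of Uck1 were shared. The list's percentile was 1.63 with a minimum of 100 counts and 94.3 with no minimum.

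Genes that build nucleotides from small precursors had higher median levels than those that salvage them. All 13 genes of purine synthesis had at least 10 counts, with a median of 97.6 CPM at percentile 98.0. Gmps, which makes GMP, led at 333 CPM (325 to 341), followed by Adss at 252 CPM, Paics at 208 CPM and Atic at 190.3 CPM. Between paralogs, Prps1 had 4.78 times the counts of Prps2 (4.31 to 5.31), or 9.29 times per kilobase. Impdh1 had 2.44 times the counts of Impdh2 (2.24 to 2.67), but 70.8% of the windows of Impdh2 were shared, so that ratio is uncertain. Of 16 pyrimidine and deoxynucleotide genes, 15 had at least 10 counts, with a median of 84.2 CPM at percentile 96.1. Cad, the enzyme of the first steps of pyrimidine synthesis, stood at 163 CPM (158 to 169) and the CTP synthase Ctps at 153 CPM (148 to 158). Ctps had 7.62 times the counts of Ctps2 (6.88 to 8.44). The ribonucleotide reductase subunit Rrm2 stood at 137 CPM and Dut at 134 CPM. The pyrimidine list left the top 5% with a minimum of 100 counts (percentile 90.4), per kilobase of exon (72.6) and without its highest member (94.4). No test of salvage against synthesis was made.

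The transcription factor Myc and genes it is known to act on were high. Myc (chromosome 15, 61985391 to 61990374, plus strand) had 14486 counts, or 681 CPM (670.03 to 692), and ranked 144th of all entries. Of 57 MYC target genes, 54 had at least 10 counts, with a median of 87.3 CPM at percentile 100.0, and 45 exceeded the median gene. The ribosome biogenesis genes Mybbp1a and Npm1 reached 837 and 738 CPM, and the mitochondrial chaperone Hspd1 646 CPM, although 35.4% of the windows of Npm1 and 39.2% of those of Hspd1 were shared. The list holds Myc itself, Hk2 and Slc29a2.

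Genes of glucose uptake and lactate production were high, with Slc2a1 far above the related transporter Slc2a3. All 23 genes of glucose uptake and glycolysis had at least 10 counts, with a median of 110 CPM at percentile 99.8. Slc2a1, the widespread glucose transporter (chromosome 4, 119108711 to 119137983, plus strand), stood at 184 CPM (178 to 189). Slc2a3 had 10 counts, and Slc2a1 had 390.3 times as many (212 to 815), or 807 times per kilobase. Hk2, the inducible hexokinase (chromosome 6, 82725025 to 82774454, minus strand), stood at 247 CPM (240.5 to 254), 1.57 times the counts of Hk1 (1.5 to 1.64). Ldha, which makes lactate from pyruvate (chromosome 7, 46841475 to 46855627, plus strand), stood at 560.4 CPM (550.4 to 571). Tpi1 and Aldoa stood at 479 and 381 CPM. Slc16a1 and Slc16a3, transporters of lactate, differed by 1.14 times (1.1 to 1.18). Pfkp had 2.36 times the counts of Pfkm but 0.588 times its counts per kilobase of all exons. Their longest transcripts have 4145 and 2879 bases, so the order of that pair depends on which length is used. Over protein-coding genes with under 10% of windows shared, the percentile came to 72.3. Among 9 pentose phosphate genes, 8 had at least 10 counts, with a median of 64.8 CPM at percentile 79.9 (98.0 with no minimum). Tkt led at 223 CPM, followed by Taldo1 at 119 CPM, G6pdx at 115 CPM and Rpe at 71.9 CPM.

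Mitochondrial energy genes were also high. All 21 tricarboxylic acid cycle genes had at least 10 counts, with a median of 112 CPM at percentile 99.8, and Dld, Mdh2 and Dlst stood at 489, 446 and 313 CPM. Of 39 nuclear oxidative phosphorylation genes, 36 had at least 10 counts and 3 were listed at 0, with a median of 88.8 CPM at percentile 99.8. Atp5b, the catalytic subunit of ATP synthase, led at 1431 CPM (1415 to 1447), followed by Cox4i1 at 401 CPM, Uqcrq at 325 CPM and Cyc1 at 264 CPM.

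The lists of response genes for amino acid shortage and for misfolded protein had the highest medians of the stress lists. Levels in 1 library do not show whether either response was switched on. Of 34 genes of the amino acid starvation response, 33 had at least 10 counts, with a median of 358 CPM at percentile 100.0. Together they held 1.63% of all counts. The response's central transcription factor Atf4 stood at 1149 CPM (1134 to 1163), the cationic amino acid transporter Slc7a1 at 1204 CPM (1189 to 1219) and the alanyl-tRNA synthetase Aars at 1028 CPM (1015 to 1042). Phgdh, the first enzyme of serine synthesis, reached 1536 CPM, although 55.7% of its windows were shared. All 20 endoplasmic reticulum stress genes exceeded the median gene, with a median of 371 CPM at percentile 100.0 and 1.36% of all counts. The chaperones Hspa5, Calr and Hsp90b1 stood at 3955, 1658 and 1201 CPM, and the disulfide isomerase Pdia3 at 1138 CPM.

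The oxidative stress, autophagy and heat shock lists had high medians as well, though the first and last were uneven. Of 26 NRF2 and oxidative stress genes, 21 had at least 10 counts, with a median of 118 CPM at percentile 99.9. The cystine transporter Slc7a11 stood at 528 CPM (518 to 537), the ferritin genes Ftl1 and Fth1 at 1146 and 747 CPM and the peroxiredoxin Prdx1 at 448 CPM. Ftl1 shared 70.2% of its windows with other genes, and Nqo1, a widely used NRF2 target, had 17 counts. While 14 of the 26 exceeded the median gene, Gsta1 had 3 counts and Gpx2, Gsta2, Gsta3 and Gstp1 were listed at 0. Of these, Gsta1, Gsta2 and Gstp1 shared 88.2%, 54.9% and 58.3% of their windows. All 33 autophagy and lysosome genes had at least 10 counts, with a median of 89.7 CPM at percentile 99.8. Sqstm1 led, followed by the lysosomal membrane protein Lamp1 at 659 CPM, the protease Ctsb at 448 CPM and Gabarap at 357 CPM. Nufip1, described as a receptor for the autophagy of ribosomes (chromosome 14, 76110891 to 76137379, plus strand), stood at 44.3 CPM (41.6 to 47.3), close to the median gene. Of 15 heat shock genes, 12 had at least 10 counts, with a median of 112 CPM at percentile 99.0, or 92.4 over protein-coding genes with under 10% of windows shared. Hsp90aa1 and Hspa8, at 944 and 747 CPM, shared 55.0% and 71.2% of their windows, and Hsph1 stood at 218 CPM. While 10 of the 15 exceeded the median gene, Hspa1b had 87 counts and Hspb1 12, with 58.1% and 49.1% of windows shared. Hspa1a, Hspa4l and Hspb8 were listed at 0, with 56.0% of the windows of Hspa1a shared.

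Inflammatory and interferon genes were prominent. Of 38 interferon response genes, 37 had at least 10 counts, with a median of 134 CPM at percentile 100.0. Isg15, a ubiquitin-like protein induced by interferon, stood at 602 CPM (592 to 613), the chemokine Cxcl10 at 441 CPM (432 to 450.1), and Oasl1 and Ifi27 at 368 and 367 CPM. Of 28 NF-kB and cytokine genes, 23 had at least 10 counts, with a median of 91.5 CPM at percentile 99.2. The prostaglandin synthase Ptgs2 reached 1665 CPM (1648 to 1683) and the neutrophil chemokine Cxcl5 1000.3 CPM (987 to 1014), followed by Cxcl3 at 479 CPM and Tnfaip2 at 414 CPM. Cytokine genes themselves were uneven. Il6 had 208 counts, against which Cxcl5 had 102 times as many (89.2 to 118), Cxcl1 had 1 count and Tnf was listed at 0. Antigen presentation genes lay near the middle, with 12 of 15 at 10 counts or more, a median of 37.2 CPM and percentile 47.2 (95.1 per kilobase). The class I genes H2-D1, B2m and H2-K1 stood at 903, 866 and 792 CPM and Tapbp at 183 CPM. The peptide transporter Tap1 had 16 counts and Tap2 9, and the immunoproteasome genes Psmb9 and Psmb8 had 1 and 0. Of 27 STAT3 and acute phase genes, 14 had at least 10 counts and 10 were listed at 0, with a median of 33.2 CPM at percentile 38.7. Junb led at 728 CPM, followed by Pim1 at 108 CPM, Stat3 at 95.2 CPM and Socs2 at 67.2 CPM.

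Growth signalling genes downstream of MAPK and YAP were high. Of 29 MAPK and immediate early genes, 27 had at least 10 counts, with a median of 142 CPM at percentile 100.0. Egr1 stood at 668 CPM (657 to 679), Klf6 at 567 CPM and Dusp6, a phosphatase induced by ERK signalling, at 463 CPM. Fosl1, at 484 CPM, had 18.1 times the counts of Fos (16.6 to 19.7), but exons of another gene overlapped 57.2% of its exonic bases. All 20 YAP target genes had at least 10 counts, with a median of 136 CPM at percentile 100.0, led by the receptor Axl at 599 CPM (588 to 609), Myof at 566 CPM, Ankrd1 at 377 CPM and Amotl2 at 185 CPM. Of 24 hypoxia genes, 22 had at least 10 counts, with a median of 53.5 CPM at percentile 80.9. Vegfa stood at 669 CPM (658 to 680.3), Ndrg1 at 483 CPM and Ero1l at 183 CPM. All 22 p53 target genes had at least 10 counts, with a median of 56.4 CPM at percentile 84.4, and Sesn2, Cdkn1a, Plk2 and Mdm2 stood at 195, 145, 137 and 107 CPM. With no minimum, the hypoxia list came to percentile 99.9 and the p53 list to 99.9, and over protein-coding genes with under 10% of windows shared the hypoxia list came to 95.5.

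Genes of DNA replication and mitosis had list medians somewhat above the median gene, with 25 of 34 and 22 of 36 members above it. All 34 DNA replication genes had at least 10 counts, with a median of 53.6 CPM at percentile 86.2 (100.0 with no minimum, 96.1 per kilobase, 56.7 with a minimum of 100 counts). The replicative helicase genes Mcm2, Mcm3, Mcm7 and Mcm4 stood at 297, 264, 260.5 and 204 CPM. Of 36 mitosis genes, 35 had at least 10 counts, with a median of 44.9 CPM at percentile 68.6 (100.0 with no minimum, 31.3 with a minimum of 100 counts). Top2a stood at 365 CPM (357 to 373), Ect2 at 211 CPM, Anln at 194 CPM and Cdk1 at 142 CPM. Fatty acid synthesis genes had a higher median than cholesterol synthesis genes, with no test of the difference. Fatty acid synthesis had a median of 75.3 CPM over 13 of 14 genes at percentile 91.9. Its highest members were Fasn at 375 CPM (367 to 384), Me1 at 327 CPM, Acly at 260.3 CPM and Scd1 at 194 CPM. Cholesterol synthesis had a median of 38.6 CPM over 23 of 24 genes at percentile 52.2, with Srebf2 at 187 CPM, Msmo1 at 117 CPM and Sqle at 91.6 CPM. With no minimum these 2 lists came to percentiles 99.8 and 99.1, and with a minimum of 100 counts to 97 and 20.6.

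The cells carried keratins and E-cadherin alongside mesenchymal genes. Of 23 ductal epithelial genes, 15 had at least 10 counts, with a median of 138 CPM at percentile 99.9. Krt18, Krt8, Krt7 and Krt19 stood at 1819, 797, 550.2 and 418 CPM, with 23.5% of the windows of Krt8 shared. The epithelial adhesion gene Cdh1 had 3.53 times the counts of the mesenchymal Cdh2 (3.37 to 3.7), and Krt18 3.65 times those of vimentin, Vim (3.58 to 3.73). Per kilobase of all exons these ratios were 6.23 and 12.1. The longest transcripts differ less in length, at 4430 bases for Cdh1, 4843 for Cdh2, 1437 for Krt18 and 2193 for Vim. The size of both ratios therefore depends on the length used. Of the other epithelial genes, Epcam had 2 counts and Cldn4 and Cldn7 were listed at 0. Of 30 TGF-beta and mesenchymal genes, 25 had at least 10 counts, with a median of 54.9 CPM at percentile 83.5 (99.5 with no minimum). Spp1 led, followed by fibronectin, Fn1, at 878 CPM (866 to 891), Vim at 498 CPM and Skil at 400.2 CPM. This list was uneven too: 14 of the 30 exceeded the median gene, while Snai1 had 8 counts and Tgfbi and Twist2 were listed at 0.

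Markers of the human PDAC subtypes were split. Of 21 classical subtype genes, 10 had at least 10 counts and 8 were listed at 0, among them Tff2, Agr2 and Muc5ac. The 10 had a median of 38.8 CPM at percentile 50, and over all 21 the median was 0.235 CPM. The endodermal transcription factors Hnf4a, Foxa2 and Gata6 stood at 70.4, 65.6 and 65.3 CPM and Anxa10 at 215 CPM. Of 21 basal-like genes, 5 had at least 10 counts and 13 were listed at 0, among them Krt5, Krt14 and Trp63. The 5 had a median of 184 CPM at percentile 98.7, with Hmga2 at 555 CPM, the EGFR ligand Areg at 301 CPM and Anxa8 at 13.1 CPM. That call rests on few genes, since the percentile was 5.22 with no minimum and 86.8 without Hmga2. Matrix proteases and inhibitors had a median of 44.2 CPM over 13 of 22 genes at percentile 61.5. Their highest members were the urokinase receptor Plaur at 504 CPM, Ctsb, Ctsl at 339 CPM and Timp2 at 258 CPM.

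Most members of the CAF, leukocyte, endothelial, acinar and red blood cell lists had under 10 counts. Of 33 CAF markers, 14 had at least 10 counts, with a median of 3.15 CPM at percentile 0.025. Col1a1 had 29 counts and Acta2 4, while Col1a2, Col3a1, Dcn, Lum and Postn were listed at 0. The highest were the membrane protease Mmp14 at 173 CPM, Fbln2 at 121 CPM, Gsn at 58.0 CPM and Pdgfra at 34.2 CPM. The list's percentile was 15.3 with no minimum and 39.6 with a minimum of 100 counts. Of 21 macrophage and leukocyte markers, 17 had under 10 counts, and the 4 others had a median of 10.8 CPM at percentile 7.6. Mrc1, the macrophage mannose receptor, stood highest at 271 CPM (264 to 278), beside Cd14 at 15.9 CPM, Cd68 at 5.69 CPM and the pan-leukocyte Ptprc at 1 count. Of 12 endothelial markers, 4 had at least 10 counts, with a median of 0.987 CPM at percentile 0.07 (27.3 with no minimum). Flt1 alone among them was near the median gene, at 33.5 CPM (31.1 to 36.0). Of 18 listed acinar markers, 3 had at least 10 counts, with a median of 0.658 CPM at percentile 0.15, led by Cel at 0.752 CPM. Of 8 red blood cell and serum genes, 1 had at least 10 counts, Alas2 at 1.13 CPM, and no percentile was computed.

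Classes of RNA that depend on library preparation were also listed. All 75 cytosolic ribosomal protein genes had at least 10 counts, with a median of 229 CPM at percentile 100.0 and 2.87% of all counts. In 65 of them at least 10% of windows were shared. The 13 genes of the mitochondrial genome held 1.09% of all counts, and the 11 with at least 10 counts had a median of 778 CPM at percentile 100.0, led by mt-Co1 at 5582 CPM with 44.1% of windows shared. mt-Nd2, mt-Nd1 and mt-Cytb stood at 1232, 1137 and 1097 CPM. Of 18 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 5 had at least 10 counts, with a median of 0.752 CPM at percentile 0.055 (28.5 with no minimum), led by Hist1h1c at 2.26 CPM.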

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

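All alternatives here were chosen after seeing the data. The alternatives set earlier for ratios between media (pseudocount, scaling, fold threshold, matched random lists and the authors' fold changes) were not run, because 1 library gives no ratio. No paired analysis was possible because 1 library was used. The number of lists below the 5th percentile was 4, against 1 with no minimum (acinar, 3.94) and 1 with a minimum of 100 counts. With no minimum, undetected genes enter the random lists too. With a minimum of 100 counts the endothelial, acinar and histone lists had fewer than 3 members left and gave no value, the CAF marker list came to 39.6, and the 1 list below was another, nucleoside transport and salvage at 1.63. The acinar list without its highest member and the histone list over uniquely mappable genes gave none either. The 19 lists above the 95th percentile came to between 17 (without the highest member) and 26 (no minimum), and 15 of the 19 stayed above it under every alternative. Of 180 list percentiles under 5 alternatives, 24 crossed a threshold, 12 of them with no minimum, and 0 went from one end to the other. The cause of the other moves was not tested. Genes with at least 10 counts numbered 11569, against 13927 with at least 1 and 9780 with at least 100. Depth limits single genes under about 100 counts, where the 95% interval reaches 18.6% below and 21.6% above the count.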

Other observations

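The genes in this paragraph, apart from Ldha and the p53 targets, lie outside the lists and were chosen after their values were seen. The glutamine transporter Slc38a2, a known ATF4 target, stood at 1242 CPM (1227 to 1257), the transporter Slc1a5 at 217 CPM (211 to 223) and glutamine synthetase, Glul, at 101 CPM (96.5 to 105). The tumour suppressor Cdkn2a stood at 233 CPM (226 to 239). Trp53 stood at 15.1 CPM (13.5 to 16.8), below the median gene. All 22 p53 targets in the list had at least 10 counts and 15 exceeded the median gene, but Fas had 29 counts and Gdf15 41. The surface receptors Epha2 and Tnfrsf12a stood at 1389 and 1267 CPM, the membrane protein Emp1 at 1389 CPM and the interferon-inducible Rnf213 at 1665 CPM. The lactate dehydrogenase subunit Ldhb was listed at 0 beside Ldha at 560.4 CPM, with 19.2% of its windows shared.

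Of the tests below, the length test of the mitochondrial genes, the permutation test of their shared windows and the interval limits for metabolic genes were chosen after the result was seen. The others were set before the shared windows and overlaps were seen, but after the counts. No biological explanation was tested, since 1 library gives no contrast.

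Ribosomal protein genes, whose products mostly enter the ribosome in equal numbers, spread from 33 to 83576 counts around a median of 4881, with 16 of 75 under 0.1 times the median. Discarding of reads shared with near-identical copies may be part of this: across genes, which are not independent replicates, Spearman's rho between shared windows and count was -0.28 (permutation p = 0.014, adjusted 0.041 over 3 correlations, bootstrap interval -0.47 to -0.072). The 16 low genes themselves differed little from the rest, with a median of 40.8% of windows shared against 34.8% in the others. With 32-base windows rho was -0.19 (permutation p = 0.11, adjusted 0.11). Transcript length gave a rho of 0.25 (p = 0.028, adjusted 0.043, interval 0.03 to 0.45). Neither reached the size of 0.3 set for a main cause, and both stay open.

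Of 13 mitochondrial genes, 6 were listed under 1000 counts, while the other 7 had more than 3000. Low counts of short genes stay open. The 6 high genes of 957 bases or more are longer than every low gene, the longest of which has 784 bases. But 3 of the low genes, mt-Co2, mt-Co3 and mt-Atp6, are longer than mt-Nd6, which has 519 bases and 3137 counts. Per kilobase of exon, the low genes stood at 13.6 CPM or less and the high genes at 284 CPM or more. Counts in simple proportion to length would not give that gap, but a steeper loss of short transcripts was not tested. Another candidate explanation is that reads matching near-identical nuclear copies were discarded, since a median of 98.9% of windows in the low genes were shared, against 2.7% in the high genes (exact two-sided permutation p = 0.037). The explanation stays open too, because mt-Atp8, listed at 0, shared 0.0% of its windows, although the genome outside annotated transcripts was not searched. The high genes mt-Nd4 and mt-Co1 had 16557 and 118732 counts with 61.4% and 44.1% of windows shared. Reads from their other windows could still be counted, so these genes do not decide the question. A split of the low genes by their shared windows was also tried and left out, since it picked genes by the value it tested.

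Of 372 members of 12 lists of basic metabolism and growth, 9 had under 10 counts: Atp5a1, Ndufs3, Uqcrc1, Pgm2, Plk4, Wdr74 and Dusp2 at 0, Kif11 at 3 and Nme2 at 7. In the GENCODE M21 annotation, 0 of the 9 had 50% or more of their exonic bases overlapped by exons of another gene (exact upper limit 33.6%). Among the 363 others, 6 had (1.65%). Within that annotation, this argues against shared exons as the cause for most of the 9. The annotation behind the counts is not given, so overlaps in it stay open. For reads shared with near-identical copies elsewhere, 0 of the 9 had 50% or more of windows shared, against 28 of 363 (7.71%), but copies outside annotated transcripts were not searched, so this stays open. For Nme2, at 48.9% overlap, exon sharing stays open. One-sided Fisher's exact tests for a higher share gave p = 1.0 in both cases, which a count of 0 always gives, and exclude nothing.

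Counts from 9 to 59 were multiples of 3 in 564 of 1417 genes, or 39.8% (Wilson 95% interval 37.3 to 42.4), against 33.3% of whole numbers in that range. The range starts on a multiple of 3 and more genes held its lower counts, so 33.3% is somewhat low as a comparison. From 60 to 299 the share was 34.7% (32.6 to 36.9), and from 300 to 1999 it was 32.9% (31.7 to 34.2). The ranges were chosen after seeing the data. Gapdh, often used as a reference gene, had 425 counts, or 19.98 CPM (18.1 to 21.98), with 80.0% of its windows shared, beside Actb at 1669 CPM.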
